A study of Mus musculus with 20 samples.

How the data were processed

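RNA of 10 mouse pluripotent lines was hybridized to 20 Agilent arrays in 1 colour (Cy3), with 2 arrays per line on 3 slides of 8, 8 and 4 arrays. Per the labels, the cells grew in 2i medium without feeder cells and without treatment, and total RNA was prepared with RNeasy columns. The labels give each iPSC line a quality grade without saying how it was measured. Per the file headers, the scanner files of array design 028005 were made with Feature Extraction 10.1.1.1, which gave each spot's intensity after background subtraction and spatial detrending, and the probe coordinates are those of mm9. The deposited value table holds log2 values whose columns have nearly equal distributions, as quantile normalization by the authors would leave them. The medians of its 20 columns run from 6.2663 to 6.2801, their lowest values from 4.0725 to 4.1659 and their highest values are all 19.0963. Its ranks follow the scanner's median signal (Spearman correlation 1, rounded), and no centring of genes was seen, so its values have no direction to undo. The submitters' processing notes name limma and no version.

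The processed signal of the scanner files was used. Of 62976 spots, 59305 were not controls. Repeated spots were averaged for 432 probes, which left 55681 probes, of which 26413 matched a current gene symbol through their RefSeq accession, 3093 changed symbol and 55249 had a chromosome. Probes kept the names of the files where no match was found. Values flagged by the scanner software were set to missing, which touched 198 probes, and 0 probes were saturated. Log2 signals were scaled by the 75th percentile of each array, a signal of 587 to 1076. Probes well above background on at least 4 of 20 arrays were kept (38756), and the brightest probe stood for each gene, which gave 27069 genes. Between 49.7% and 77.5% of probes per array were well above background, and the number of arrays limits the precision. The lowest correlation between the 2 arrays of a line was 0.977.

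The 2 arrays of a line were averaged, so that the line was the replicate. Limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8) fitted 1 model to all 10 lines with the groups poor (3 lines), good (2), high (2) and ESC (3), and a second with SNEL (3), OSKM (4) and ESC (3), and 6 comparisons were read from them. P values were adjusted by Benjamini and Hochberg's method over all genes, with a threshold of 0.05, and a second adjustment was made over each list alone. The second was made within each list and comparison and not over the 24 lists and 6 comparisons together. Some of its calls can therefore come by chance. A named gene in more than 1 list was given its smallest value. Slides hold several groups, so the comparisons were also made with slide as a block on the 20 arrays, with slide effects estimated within lines removed, and within each slide. A group with 1 line left is assumed to vary like the other groups.

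The gene lists, the named-gene rule, the comparisons and most alternatives were fixed before the data were examined. The rule named, per comparison, the 10 largest rises and falls among genes past the threshold whose lines did not overlap, or the 5 genes with the smallest p where fewer than 5 passed. It added list members past the threshold over all genes or over the list alone (at most 6 per list), the 8 reprogramming factors, the genes of the Dlk1-Dio3 locus, the gene of H2A.X and sex-linked genes. Rian had no probe under that name, though probes named by their position lie between Meg3 and Mirg, and Rtl1 did not pass the filter. Other list members are given as examples and were chosen after their values were seen. Of 25 lists, 24 were tested with limma's camera at a preset correlation of 0.01, adjusted over 144 tests. Of these 27 passed, and 0 passed with an estimated correlation (lowest adjusted p = 0.987). Sex-linked genes were described per line only. For 0 of the 27 did the median, the mean and the test differ in sign.

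Distances between lines were root mean square log2 differences over all genes and were tested with exact two-sided permutation tests. Group labels were moved over fixed distances to the ESC lines, so the test of iPSC against ESC lines is not truly exact. Chromosome medians were taken over the genes of each chromosome after subtracting the mean of the ESC lines (of the other ESC lines, for an ESC line) and the median of the line. Correlations across the 10 lines were tested with 100000 permutations.

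The test was checked on simulated data with the spread of the real lines, where 200 genes per draw were changed by known folds. Genes were drawn independently and the 200 were changed together, so the shares need not hold where fewer genes change. Over 3 draws the false calls per comparison ran from 21 to 27. At 2-fold, 4-fold, 8-fold and 16-fold, limma called 24.7%, 60.7%, 84.7% and 88% of the changed genes for poor lines against ESC lines, 20.7%, 59.3%, 74.7% and 80.7% for good against ESC, 12%, 59.3%, 76% and 86% for high against ESC, 18.7%, 55.3%, 81.3% and 83.3% for high against poor, 28.7%, 64%, 87.3% and 92% for good and high against poor, and 30%, 72.7%, 88.7% and 93.3% for SNEL against OSKM.

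The alternatives were quantile normalization, normexp background correction with an offset of 50, the authors' value table, no filter or a filter of all 20 arrays, the mean of a gene's probes, eBayes with trend, a 2-fold minimum, X and Y genes left out, the 20 arrays as independent samples or with the line as a random block, a block of array numbers, the origin of the lines as a covariate, only the groups compared, each array number and each line left out, other distance measures and other references for chromosomes. Removal of slide effects, fits within slides, the fibroblast mean as a covariate, KH2_OSKM by its second array, a mean level above −3 and the median of all 10 lines for the chromosome medians, and a distance without fibroblast genes and genes that follow them were chosen after the data had been seen. No array was left out.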

Results

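Expression was measured on 20 arrays in 7 mouse induced pluripotent stem cell (iPSC) lines and 3 embryonic stem cell (ESC) lines, with 2 arrays per line. The iPSC lines had been made with 1 of 2 sets of transcription factors, OSKM (Oct4, Sox2, Klf4 and Myc) or SNEL (Sall4, Nanog, Esrrb and Lin28), and the labels grade them as poor, good or high quality. The 3 poor lines were Nanog-GFP OSKM#2, Oct4-GFP OSKM#2 and KH2_OSKM. The 2 good lines were BC_2 OSKM and Nanog-GFP SNEL#3, the 2 high lines were Nanog-GFP SNEL#2 and Oct4-GFP SNEL#1, and the 3 ESC lines were KH2 ESCs, Nanog-GFP ESCs and Oct4-GFP ESCs. Nothing in the labels says that the 2 arrays of a line came from separate cultures, so each value below is a mean over lines, and n counts lines. Levels are log2 signals relative to the 75th percentile of the array. Between 49.7% and 77.5% of an array's probes were well above background, and the number of arrays limits the precision of every value. As line means this share was 51%, 58.1% and 59.7% in the SNEL lines and 62% to 68.3% in all other lines. Every poor line (63.3%, 66.9% and 68.3%) also lay above every good and high line. Comparisons of factors and of poor with good and high lines are therefore confounded with this share. The quality grade and the factors are partly confounded, since all 3 poor lines are OSKM and both high lines are SNEL.

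The first question was how near each iPSC line lay to the ESC lines over all 27069 genes tested. The mean root mean square log2 distance to the ESC lines was 0.787 ± 0.046 (SD, n = 7) for iPSC lines, against 0.636 ± 0.057 (n = 3) for each ESC line to the other ESC lines. The difference of 0.151 had an exact two-sided permutation p of 0.00833, the smallest that the 120 splits of the lines allow. The permutation moved group labels over distances already measured to the ESC lines. ESC lines share their pairwise distances and are not exchangeable with iPSC lines, so this p is no exact test of the grouping. The same holds for the other p values of iPSC against ESC lines below. The means were 0.797 ± 0.055 (n = 3) for poor, 0.8 ± 0.061 (n = 2) for good and 0.76 ± 0.032 (n = 2) for high lines. Poor lines differed from good and high lines together (0.78 ± 0.046, n = 4) by 0.018, less than the spread between lines (exact permutation p = 0.6). KH2_OSKM had the largest distance, 0.852, close to the 0.843 of BC_2 OSKM, and its own 2 arrays lay 0.922 apart, against 0.494 to 0.723 in the other lines. With slide effects removed the difference between iPSC and ESC lines was 0.133 (exact permutation p = 0.0167). The difference rested on single ESC lines, at 0.051 without Oct4-GFP ESCs (exact permutation p = 0.0833), 0.093 without KH2 ESCs (exact permutation p = 0.0278) and 0.308 without Nanog-GFP ESCs (exact permutation p = 0.0278).

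**Figure D1:**
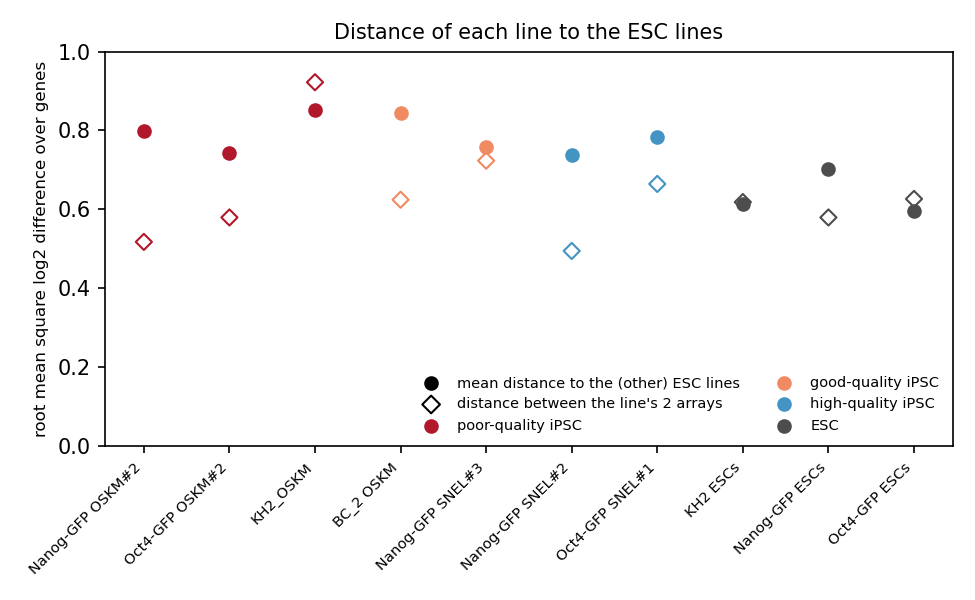
Distance of each line to the ESC lines (filled circles, root mean square log2 difference over all genes tested) and between the 2 arrays of the line (open diamonds). The iPSC lines average 0.787 and the ESC lines 0.636.

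Poor lines against ESC lines ask which genes set the lines of the lowest grade apart from ESCs. Genes of fibroblasts, the cell type from which iPSCs are commonly made and which is also used as feeder cells, were lower in poor lines. The collagen genes Col1a2 (−2.99 ± 0.89 against 1.46 ± 0.41, SD, n = 3 and 3) and Col3a1 (−4.96 ± 0.83 against −0.34 ± 0.56), and Acta2, the smooth muscle actin of contractile fibroblasts (−3.88 ± 0.11 against −0.27 ± 1.42), fell by 4.45, 4.62 and 3.61 on the log2 scale (adjusted p = 0.00383, 0.00339 and 0.00383 over the list alone). Meg3, the noncoding RNA expressed from the maternal copy of the imprinted Dlk1-Dio3 locus, was 1.53 ± 1.47 in poor and 4.79 ± 0.36 in ESC lines, and fell by 3.26 ± 0.76 (SE; adjusted p = 0.0105 over the list alone). Mirg, the noncoding microRNA host transcript at the other end of the noncoding part of the locus, fell by 3.14 ± 1.05 (adjusted p = 0.0341 over the list alone). No adjustment was made over the lists and comparisons together, so calls over a list alone, here and below, can come by chance. The protein-coding genes of the locus, Dlk1 (−0.25 ± 0.56) and Dio3 (−0.06 ± 0.33), differed by less than their errors, and the list of the locus, all 4 measured genes lower, did not pass (median −1.70, camera adjusted p = 0.0803).

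As groups, 19 of the 23 fibroblast genes were lower in poor lines than in ESC lines, with a median of −1.10 (camera adjusted p = 3.84e-09, adjusted p = 0.987 with an estimated correlation). Over all genes 0 of them passed limma's threshold, and 12 fell when adjusted over the list alone. They included Col6a1, a subunit of collagen VI (−3.17 ± 0.47), Dcn, the matrix proteoglycan decorin (−2.76 ± 0.53, above background on 1 of 6 poor arrays), and Postn, the matrix protein periostin (at least 4.47-fold lower). Of the 23 fibroblast genes, 16 were above background on all 6 poor arrays, while Postn and Lum were on 0. The filter kept such dim genes through other lines, which favours a lower value in poor lines. Genes of the two-cell-like state, which mark rare cells of ESC cultures, were higher in 13 of 15 cases, with a median of 2.97 (camera adjusted p = 0.000658, adjusted p = 0.987 with an estimated correlation). Zscan4f, a zinc finger gene of that state, had 3.85 ± 2.35 and the deubiquitinase gene Usp17lb 3.74 ± 1.34, and 0 of the 15 passed over all genes or adjusted over the list alone. Germline genes were higher in 19 of 23 cases, with a median of 1.07 (camera adjusted p = 4.9e-05, adjusted p = 0.987 with an estimated correlation), among them Xlr4b (4.23 ± 1.16) and the X-linked homeobox gene Rhox5 (2.10 ± 0.74). Again 0 passed over all genes or adjusted over the list alone. Targets of p53 were higher in 19 of 23 cases, by a median of 0.18 (camera adjusted p = 0.0119, adjusted p = 0.987 with an estimated correlation). Phlda3, a p53 target that restrains Akt, was 4.69 ± 0.11 against 3.89 ± 0.21 and rose by 0.80 ± 0.15, the 1 member that passed adjusted over the list alone (adjusted p = 0.0191). Of 143 ribosomal protein genes, 120 were lower, with a median of −0.10 (camera adjusted p = 0.00127, adjusted p = 0.987 with an estimated correlation), but the median was 0 with quantile normalization and in the authors' value table. Among other imprinted genes, the growth factor Igf2 fell by 1.69 ± 0.28 (adjusted p = 0.0114 over the list alone), and was above background on 2 of 6 poor arrays. It differed by −3.03 within slide 1 and −0.63 within slide 2, but the ESC array of slide 1 is of KH2 ESCs, the ESC line with the most Igf2 (−3.73, against −4.50 and −4.87).

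Over all 27069 genes, limma called 0 genes higher and 0 lower in poor lines, with 2633 genes at an unadjusted p under 0.05, where chance gives 1353. The 5 genes with the smallest p were Gm4728 (at least 1.45-fold higher, adjusted p = 0.0541), AI662270 (at least 2.19-fold higher, adjusted p = 0.0541), Ccdc80, a secreted matrix protein (at least 9.52-fold lower, adjusted p = 0.168), Sash3, a lymphocyte adaptor (at least 2.62-fold higher, adjusted p = 0.191) and Thbs1, the matrix protein thrombospondin (at least 19-fold lower, adjusted p = 0.191). These bounds compare the bright group's mean over all its arrays with the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background. Across the 10 lines the correlations of these genes with the fibroblast list were 0.94 for Thbs1 and for Ccdc80, −0.77 for AI662270, −0.74 for Gm4728 and −0.59 for Sash3. The genes were chosen for a difference between poor and ESC lines, and the list mean differed between the same lines (−0.71 against 0.97). The choice thus favours such correlations, and they are no separate evidence of a relation. Grade and fibroblast signal were not separated for Thbs1 and Ccdc80. In the good lines, where fibroblast genes were as low as in poor lines, Sash3 (−6.30 and −6.26) and Gm4728 (−6.80 and −6.75) were lower than in poor lines (−4.74 to −4.58 and −5.81 to −5.20). The values of the 3 poor and 3 ESC lines did not overlap in 4830 genes, or 17.8%, where chance gives 10%. The 3 slides held arrays of several groups, but slide 1 held 1 ESC array, of KH2 ESCs, and slide 2 held 1 of each other ESC line, so values within slides against ESC lines also differ by ESC line. With slide as a block limma called 11 genes, 6 higher and 5 lower. This fit, here and below, was made on the 20 arrays with the line as a random block, and without slide it called 40 genes. Its counts are therefore not comparable with those of the line averages. Within slide 1 and slide 2 the fibroblast median was −1.36 and −0.98, Col1a2 was −4.56 and −4.63, Meg3 was −3.38 and −3.23, the two-cell-like median was 3.54 and 2.66, the germline median was 1.66 and 0.56, the p53 target median was 0.32 and 0.08, and the ribosomal median was −0.16 in both. The calls of Meg3 and of the 6 fibroblast genes named held with any 1 line left out. The two-cell-like median was 2.12 (adjusted p = 0.0625) without Oct4-GFP OSKM#2, and the germline median was 0.56 without KH2 ESCs. The p53 target median was 0.42 without Nanog-GFP ESCs, 0.14 (adjusted p = 0.0927) without KH2 ESCs and 0.12 (adjusted p = 0.286) without Oct4-GFP ESCs. Adjusted over the list alone, Mirg no longer passed without Nanog-GFP OSKM#2, KH2_OSKM or any 1 of the ESC lines (adjusted p = 0.0609 to 0.122), Phlda3 without Oct4-GFP OSKM#2, KH2_OSKM, KH2 ESCs or Oct4-GFP ESCs (0.0746 to 0.114), and Igf2 without Nanog-GFP OSKM#2 (0.0598) or Oct4-GFP OSKM#2 (0.0644). Leaving out a line of another group changed the count of 0, to 1 without BC_2 OSKM or Nanog-GFP SNEL#3 and to 2 without Nanog-GFP SNEL#2 or Oct4-GFP SNEL#1.

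**Figure D2:**
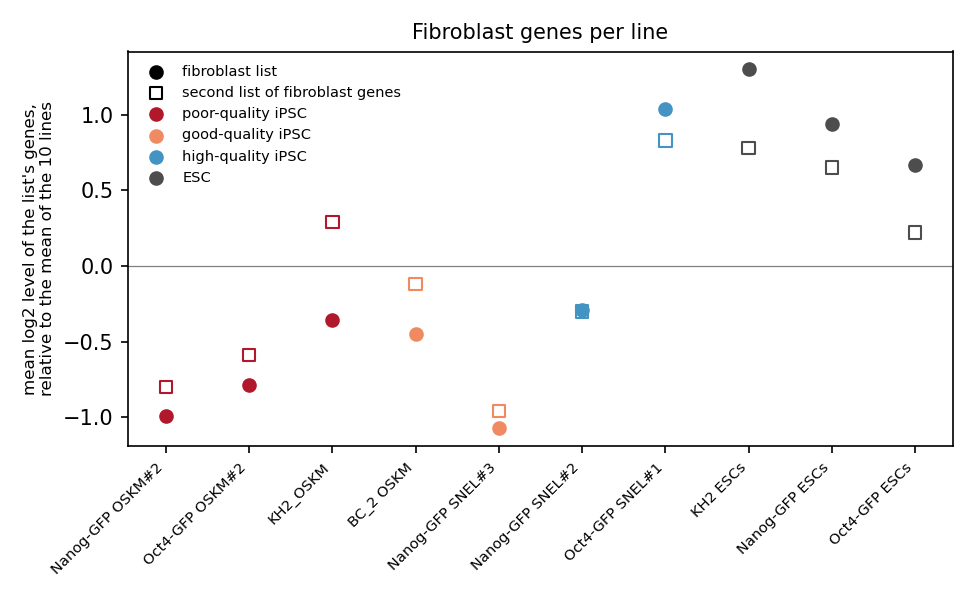
Mean of the fibroblast list (filled circles) and of a second list of abundant fibroblast genes (open squares) in each line, as log2 signal relative to the mean of the 10 lines. The fibroblast mean runs from −1.07 in Nanog-GFP SNEL#3 to 1.30 in KH2 ESCs, and Oct4-GFP SNEL#1 lies at 1.04.

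Good lines against ESC lines ask the same of lines of the middle grade. Fibroblast genes were lower here as well, in 21 of 23 cases with a median of −1.35 (camera adjusted p = 3.71e-12, adjusted p = 0.987 with an estimated correlation), and 12 fell adjusted over the list alone while 0 passed over all genes. Col1a2 fell by 4.24 ± 0.90 (SE, n = 2 and 3), Col6a1 by 2.47 ± 0.53, Acta2 by 3.48 ± 0.75 and S100a4, a calcium-binding protein of fibroblasts, by 0.87 ± 0.19, each with adjusted p = 0.00954 over the list alone. Meg3 was 6.09 ± 0.62 (SD, n = 2) in good lines and 4.79 ± 0.36 (n = 3) in ESC lines, a difference of 1.30 ± 0.85 that did not pass the test. The placental hormone gene Prl3d1 fell by 0.98 ± 0.22 (adjusted p = 0.0248 over the list alone), was above background on 3 of 4 good arrays, and differed by −0.15 within slide 2.

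Genes of naive and core pluripotency were higher in good lines in 22 of 30 cases, with a median of 0.10 (camera adjusted p = 0.0395), germline genes had a median of 0.19 (adjusted p = 0.0332), p53 targets 0.27 with 19 of 23 higher (adjusted p = 7.72e-06), ribosomal proteins 0.07 with 106 of 143 higher (adjusted p = 0.00133, but median 0.01 and not passing with quantile normalization or in the authors' value table), and core histones −0.28 with 35 of 47 lower (adjusted p = 0.0448). Each of these 5 had adjusted p = 0.987 with an estimated correlation, and 0 of their members passed over all genes or adjusted over the list alone. Limma called 0 genes higher and 0 lower, with 1665 at an unadjusted p under 0.05. The smallest p belonged to Slc24a3, a sodium, potassium and calcium exchanger (−1.19 ± 0.18, adjusted p = 0.563, correlation with the fibroblast list 0.92), AI662270 (at least 1.07-fold higher), Ccdc80 (at least 5.83-fold lower), ENSMUST00000124556 (−1.39, above background on 1 of 4 good arrays) and a noncoding probe on chromosome 12 at 74139438 to 74139497 (at least 3-fold lower). Lines did not overlap in 20.8% of genes, where chance gives 20%. Within slides 1 and 2 Slc24a3 differed by −1.52 and −0.32, and ENSMUST00000124556 by 0.21 and −1.06. With slide as a block limma called 4 genes, 2 higher and 2 lower, against 10 in the same fit without slide. Within these slides the fibroblast median was −1.77 and −1.13, the germline median 0.78 and −0.07, the p53 target median 0.33 and 0.26, the ribosomal median 0.01 and 0.04, the core histone median −0.26 in both, and the pluripotency median 0.01 and 0.15. Without BC_2 OSKM the germline median was −0.33, the core histone median 0, the p53 target median 0.18 (adjusted p = 0.137), the pluripotency median 0.26 and the ribosomal median 0.13. Without Nanog-GFP SNEL#3 these medians were 0.90 (germline), 0.51 (p53 targets), −0.07 (pluripotency) and 0.02 (ribosomal), and the fibroblast genes Col1a2, Col3a1, Col6a1, Acta2, S100a4 and Dcn no longer passed adjusted over the list alone (adjusted p = 0.0634). The germline median was −0.05 without KH2 ESCs, 0.51 without Nanog-GFP ESCs and 0.09 without Oct4-GFP ESCs, the pluripotency median 0.05 without Nanog-GFP ESCs and 0.08 (adjusted p = 0.331) without Oct4-GFP ESCs, and the p53 target median 0.17 without Oct4-GFP ESCs. Core histones no longer passed without KH2 ESCs (adjusted p = 0.112) or Nanog-GFP ESCs (adjusted p = 0.107), nor Prl3d1 without BC_2 OSKM, Nanog-GFP SNEL#3, Nanog-GFP ESCs or Oct4-GFP ESCs (adjusted p = 0.0604 to 0.133 over the list alone). Limma called 6 genes without Nanog-GFP SNEL#3 and 1 without Oct4-GFP OSKM#2.

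High lines against ESC lines ask what distinguishes the lines of the highest grade from ESCs. Phlda3 was 4.67 ± 0.06 (SD, n = 2) in high lines against 3.89 ± 0.21 (n = 3) and rose by 0.78 ± 0.17 (adjusted p = 0.0437 over the list alone). The p53 targets as a group were higher in 20 of 23 cases, with a median of 0.26 (camera adjusted p = 4.09e-06, adjusted p = 0.987 with an estimated correlation), and Phlda3 was the 1 that passed. The p53-induced receptor gene Eda2r (0.97 ± 0.29) and the kinase gene Plk2 (1.16 ± 0.56) were among them. Meg3 (0.19 ± 0.85) and Mirg (−0.06 ± 1.17) differed from ESC lines by less than their errors, and the 3 Meg3 probes did not share a direction, at −0.32 to 0.19. The fibroblast list had a median of −0.57 with 17 of 23 genes lower, which did not pass (camera adjusted p = 0.158).

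Core histone genes were lower in high lines in 41 of 47 cases, with a median of −0.26 (camera adjusted p = 0.0195). Two-cell-like genes had a median of 2.48 with 14 of 15 higher (adjusted p = 8.24e-05), among them Zscan4f (3.18 ± 2.63), and germline genes a median of 0.61 with 20 of 23 higher (adjusted p = 0.000503), among them the homeobox gene Rhox9 (1.08 ± 0.57). All 3 had adjusted p = 0.987 with an estimated correlation, and 0 of their members passed over all genes or adjusted over the list alone. Both of the higher groups rested on Oct4-GFP SNEL#1, without which the two-cell-like median was −0.15 (adjusted p = 0.791) and the germline median −0.14. Without Nanog-GFP SNEL#2 they were 5.10 and 1.46, and the germline median was 0.24 without KH2 ESCs. Limma called 0 genes in either direction, with 1581 at an unadjusted p under 0.05. Lines did not overlap in 21% of genes, where chance gives 20%. The smallest p belonged to a noncoding probe on chromosome 8 at 108103549 to 108103608 (1.60), ENSMUST00000106505 (−2.37, above background on 1 of 4 high arrays), a noncoding probe on chromosome 9 at 34195840 to 34195899 (−0.96), Atad3aos (−1.13 ± 0.18, above background on 1 of 4 high arrays) and the zinc finger gene Zkscan4 (−0.90 ± 0.14), each with adjusted p = 0.83. The chromosome 8 probe differed by 1.94, −0.03 and 1.30 within slides 1, 2 and 3, and the other probe of its transcript by 0.18. With slide as a block limma called 0 genes, against 5 in the same fit without slide. Slide 1 holds 1 ESC array (KH2 ESCs), slide 2 holds 1 high array (Nanog-GFP SNEL#2) and slide 3 holds 1 (Oct4-GFP SNEL#1), so values within slides also differ by line. Within slides 1, 2 and 3 the two-cell-like median was 3.11, −0.57 and 4.93, the germline median 1.27, −0.35 and 1.60, the p53 target median 0.34, 0.32 and 0.21, and the core histone median −0.30, −0.34 and −0.17. Core histones no longer passed without Nanog-GFP SNEL#2 (median −0.15, adjusted p = 0.924), KH2 ESCs (adjusted p = 0.0588) or Nanog-GFP ESCs (adjusted p = 0.0714). The p53 target median was 0.40 without Oct4-GFP SNEL#1, 0.41 without Nanog-GFP ESCs and 0.17 without Oct4-GFP ESCs. Phlda3 passed adjusted over the list alone in the absence of Nanog-GFP ESCs but of no other line (adjusted p = 0.0588 to 0.258). Limma called 1 gene without Oct4-GFP OSKM#2 or without Oct4-GFP SNEL#1.

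The differences of the 3 iPSC grades from the ESC lines were related across genes, which are not independent replicates. The correlation was 0.53 between poor and good, 0.61 between poor and high and 0.58 between good and high, against 0.45, 0.45 and 0.4 in 100 simulations of unchanged groups that shared the ESC lines. The covariances were 0.143, 0.161 and 0.14, against 0.112, 0.111 and 0.112 simulated. Part of the excess of 0.031, 0.05 and 0.029 can still come from the shared ESC lines, since 3 lines cannot be split into separate sets of at least 2.

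High lines against poor lines compare the ends of the quality grading. Meg3 was 4.98 ± 1.34 (SD, n = 2) in high lines and 1.53 ± 1.47 (n = 3) in poor lines, and rose by 3.45 ± 0.85 (SE; adjusted p = 0.0144 over the list alone). Mirg was higher by 3.08 ± 1.17 (adjusted p = 0.0601 over the list alone). Dnmt3l, the cofactor of the de novo DNA methyltransferases, was 3.00 ± 0.32 against 5.22 ± 0.85 and fell by 2.22 ± 0.50 (adjusted p = 0.0345 over the list alone). The Dlk1-Dio3 list was higher in 4 of 4 measured genes, with a median of 1.72 (camera adjusted p = 0.00445, adjusted p = 0.987 with an estimated correlation), and Meg3 was the 1 that passed adjusted over the list alone.

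Fibroblast genes were higher in high than in poor lines in 19 of 23 cases, with a median of 0.62 (camera adjusted p = 6.16e-09). Between the 2 high lines the mean of the list, relative to the mean of the 10 lines, was 1.04 in Oct4-GFP SNEL#1 and −0.29 in Nanog-GFP SNEL#2. The 3 that rose adjusted over the list alone were Col6a1 (2.60 ± 0.53, adjusted p = 0.0218), Col3a1 (3.86 ± 0.85, adjusted p = 0.0218) and Col1a2 (3.32 ± 0.90, adjusted p = 0.0466). Pluripotency genes were higher in 23 of 30 cases with a median of 0.16 (adjusted p = 0.0165), and ribosomal proteins in 125 of 143 with a median of 0.14 (adjusted p = 6.48e-10, but median 0.02 and not passing with quantile normalization or in the authors' value table), and 0 members of either list passed over all genes or adjusted over the list alone. All 3 lists had adjusted p = 0.987 with an estimated correlation. Limma called 0 genes over all genes, with 1150 at an unadjusted p under 0.05, fewer than chance gives, and 0 with slide as a block. The smallest p belonged to D630011A20Rik (−1.54 ± 0.18, adjusted p = 0.708), Gm9740 (1.66, above background on 1 of 6 poor arrays), AI662270 (at least 1.32-fold lower), Ccdc85c (at least 1.13-fold lower) and 1700011M02Rik (−1.63, above background on 1 of 4 high arrays). Within slides 1 and 2 D630011A20Rik differed by −2.96 and −0.03 and Gm9740 by 3.44 and −0.08, with 1 high array on slide 2. Lines did not overlap in 16.6% of genes, where chance gives 20%. Within slides 1 and 2 the fibroblast median was 0.57 and 0.52, the Dlk1-Dio3 median 1.66 and 2.15, the pluripotency median 0.17 and 0.34, the ribosomal median 0.17 and 0.21, and Dnmt3l −2.24 and −1.93. Without Oct4-GFP SNEL#1 the Dlk1-Dio3 median was 2.16 (adjusted p = 0.0796), the fibroblast median 0.54 (adjusted p = 0.136), the pluripotency median 0.33, the ribosomal median 0.22 and Col1a2 2.06. Without Nanog-GFP SNEL#2 the fibroblast median was 1.32, the pluripotency median 0 (adjusted p = 0.708), the ribosomal median 0.05 and Meg3 2.50 (adjusted p = 0.158 over the list alone), and without KH2_OSKM the pluripotency median was 0.09 (adjusted p = 0.222). Adjusted over the list alone, the 3 collagen genes no longer passed without Nanog-GFP OSKM#2, Oct4-GFP OSKM#2 or Oct4-GFP SNEL#1 (adjusted p = 0.0565 to 0.233), nor Col1a2 without Nanog-GFP ESCs (0.0656) or Oct4-GFP ESCs (0.073). Dnmt3l passed only without Nanog-GFP OSKM#2, KH2_OSKM or Nanog-GFP ESCs (0.0511 to 0.145 without the others). Limma called 1 gene without Oct4-GFP OSKM#2 or without Oct4-GFP SNEL#1.

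Good and high lines together against poor lines ask what the lines above the lowest grade share. Meg3 was 5.54 ± 1.07 (SD, n = 4) against 1.53 ± 1.47 (n = 3) and rose by 4.0 ± 0.71 (SE; adjusted p = 0.00193 over the list alone, adjusted p = 0.888 over all genes). Mirg was 3.02 ± 1.67 against −0.56 ± 1.58 and rose by 3.58 ± 0.98 (adjusted p = 0.0129 over the list alone). Among the poor lines Oct4-GFP OSKM#2 was highest in both, with Meg3 at 3.02 against 4.04 in the high line Oct4-GFP SNEL#1, and Mirg at 0.96 against 1.04. The Meg3 probe lies at 110809678 to 110809737 and the Mirg probe at 110987569 to 110987628 of chromosome 12 (mm9). The 3 Meg3 probes gave 2.97 to 4.0, and within slides 1 and 2 the difference was 4.04 and 4.46. Dlk1 (0.22 ± 0.52) and Dio3 (0.50 ± 0.31) did not pass. Hand2, a transcription factor of heart and limb mesoderm, fell by 1.05 ± 0.25 (adjusted p = 0.0407 over the list alone), and was above background on 1 of 8 arrays of good and high lines. The size of its fall is therefore uncertain. The highest of the high lines had −4.89, within the range of the poor lines (−5.05 to −4.72). Oas1a, an interferon-induced antiviral enzyme, was 3.38 ± 0.37 against 4.34 ± 0.21 and fell by 0.96 ± 0.23 (adjusted p = 0.048 over the list alone).

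**Figure D3:**
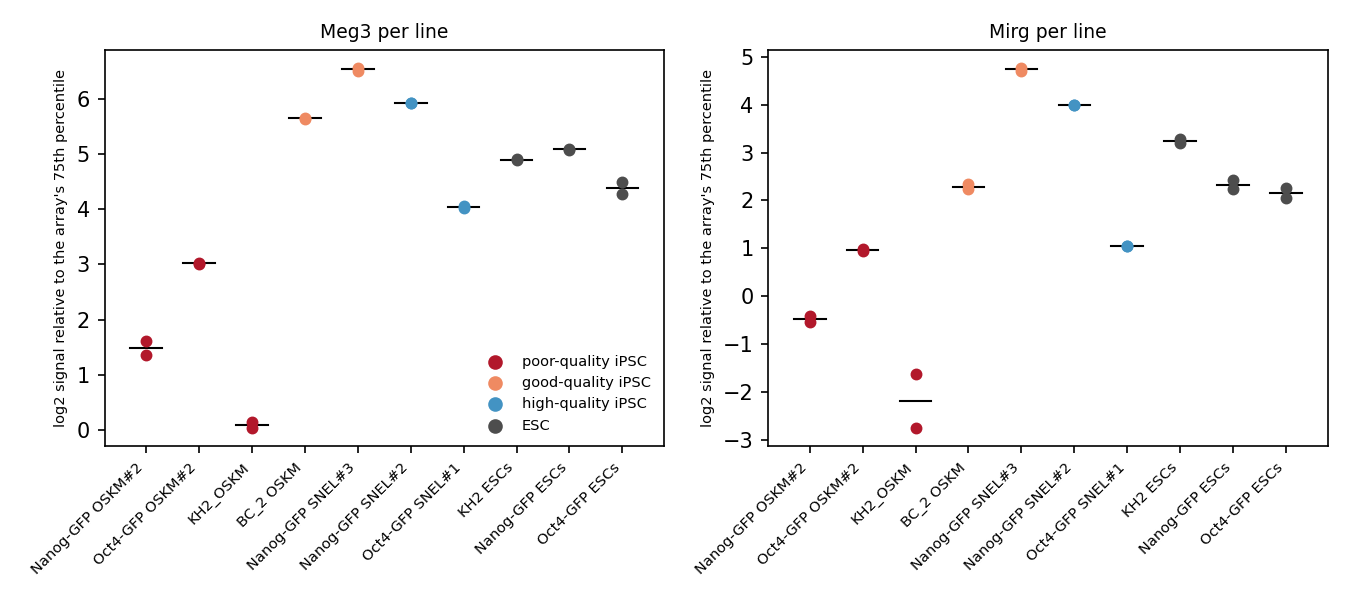
Log2 signal of Meg3 and Mirg relative to the 75th percentile of each array, by line, with dots for arrays, bars for line means and colours for groups. Meg3 averages 1.53 in poor lines, 6.09 in good, 4.98 in high and 4.79 in ESC lines.

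As groups, the Dlk1-Dio3 list was higher in good and high lines in 4 of 4 genes, with a median of 2.04 (camera adjusted p = 0.000346), and 2 of them, Meg3 and Mirg, passed adjusted over the list alone. Pluripotency genes were higher in 25 of 30 cases with a median of 0.15 (adjusted p = 0.000705), ribosomal proteins in 129 of 143 with a median of 0.16 (adjusted p = 8.75e-15, but median 0.02 and not passing with quantile normalization or in the authors' value table), and fibroblast genes in 15 of 23 with a median of 0.41 (adjusted p = 0.00358), and 0 members of these 3 lists passed either adjustment. All 4 lists had adjusted p = 0.987 with an estimated correlation. Limma called 0 genes over all genes, with 1389 at an unadjusted p under 0.05. Lines did not overlap in 5.9% of genes, where chance gives 5.71%. The smallest p belonged to D630011A20Rik (−1.10, with −2.00 within slide 1 and −0.20 within slide 2), Ccdc85c (at least 1.04-fold lower), 1700011M02Rik (−1.47), the protease inhibitor gene Stfa2 (−1.29 ± 0.20, above background on 2 of 8 arrays of good and high lines, with −2.35 within slide 1 and −0.50 within slide 2) and Gm4728 (lower, of no measurable size, since it was above background on 0 of 8 arrays of good and high lines), each with adjusted p = 0.835. With slide as a block limma called 4 genes, 1 higher and 3 lower, against 6 in the same fit without slide. The 4 were Meg3, Apod, Ube2l6 and Pramel14, the last 3 of them named after their values were seen. The calls of Meg3 and of the Dlk1-Dio3 list held with any 1 line left out, and Mirg no longer passed without KH2_OSKM (adjusted p = 0.0535 over the list alone). Hand2 passed adjusted over the list alone only without Nanog-GFP SNEL#3 or Oct4-GFP SNEL#1, and Oas1a only without Oct4-GFP SNEL#1. Within slides 1 and 2 the Dlk1-Dio3 median was 1.95 and 2.48, the pluripotency median 0.20 and 0.25, the ribosomal median 0.17 and 0.21, and the fibroblast median 0.31 and −0.02. The fibroblast median was 0.18 (adjusted p = 0.442) without Oct4-GFP SNEL#1, 0.32 (adjusted p = 0.151) without BC_2 OSKM, 0.23 without Nanog-GFP OSKM#2, 0.71 without KH2_OSKM and 0.68 without Nanog-GFP SNEL#2. The pluripotency median was 0.14 (adjusted p = 0.0789) without KH2_OSKM, 0.10 without Nanog-GFP SNEL#3, 0.23 without Nanog-GFP OSKM#2, 0.25 without Oct4-GFP OSKM#2, 0.29 without Oct4-GFP SNEL#1 and 0.32 without BC_2 OSKM. Limma called 1 gene without Oct4-GFP OSKM#2.

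SNEL lines against OSKM lines address the factors, the subject that the series title names. Fgf22, a fibroblast growth factor gene (chromosome 10, 79221282 to 79221341, mm9), was −1.84 ± 0.08 (SD, n = 3) in SNEL lines against −3.55 ± 0.18 (n = 4) in OSKM lines and rose by 1.71 ± 0.14 (SE; adjusted p = 0.0158). The difference was 2.98 within slide 1 and 0.32 within slide 2, and a second Fgf22 probe gave −0.65. Grem1, a secreted antagonist of bone morphogenetic proteins (chromosome 2, 113589227 to 113589286), was −4.37 ± 0.65 against −7.76 ± 0.22, at least 2.69-fold higher (adjusted p = 0.0345). It was above background on 3 of 6 SNEL arrays and 0 of 8 OSKM arrays, so that its signal differences of 3.52 within slide 1 and 2.90 within slide 2 give a direction and no size. Grem1 ran from −4.63 to −3.65 in ESC lines, near its level in SNEL lines, and its correlation with the fibroblast list across the 10 lines was 0.73. Ascl2, an imprinted transcription factor gene of the placental lineage (chromosome 7, 150152734 to 150152793), was 2.04 ± 0.39 against 3.67 ± 0.39 and fell by 1.63 ± 0.26 (adjusted p = 0.00182 over the list alone, adjusted p = 0.414 over all genes). It differed by −1.57 within slide 1 and −1.81 within slide 2.

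Genes of naive and core pluripotency were higher in SNEL lines in 27 of 30 cases, with a median of 0.25 (camera adjusted p = 0.00384, adjusted p = 0.987 with an estimated correlation). The values were 0.61 ± 0.30 for Nr0b1, an orphan nuclear receptor of ESCs, 0.57 ± 0.32 for Tet1, a 5-methylcytosine dioxygenase, and 0.36 ± 0.23 for Tfcp2l1, a transcription factor of naive cells. Germline genes were lower in 19 of 23 cases, with a median of −0.68 (adjusted p = 0.0395), among them Xlr4b (−2.65 ± 1.09) and Dazl, an RNA-binding protein of germ cells (−1.67 ± 0.76), but not Rhox6 (1.44 ± 0.49). Fibroblast genes had a median of 0.39 with 18 of 23 higher (adjusted p = 0.0329) and ribosomal proteins a median of 0.15 with 127 of 143 higher (adjusted p = 2.15e-08, but median 0.01 to 0.02 and not passing with quantile normalization or in the authors' value table). These 3 lists had adjusted p = 0.987 with an estimated correlation, and 0 members of these 4 lists passed over all genes or adjusted over the list alone. Primitive endoderm genes, which mark an extraembryonic lineage, were lower in 16 of 18 cases with a median of −0.56 and did not pass (adjusted p = 0.0514). They included Sox17 (−1.33 ± 0.58) and Foxa2 (−1.03 ± 0.32), transcription factors of endoderm.

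Over all genes limma called 2 genes higher in SNEL lines, Fgf22 and Grem1, and 0 lower, with 2544 at an unadjusted p under 0.05. The other 3 of the smallest p were Pigb, a mannosyltransferase of membrane anchor synthesis (at least 4.3-fold higher, adjusted p = 0.0953, above background on 0 of 8 OSKM arrays, with signal differences of 5.40 within slide 1 and 0.11 within slide 2), a noncoding probe on chromosome 4 at 118726559 to 118726618 (−2.42 ± 0.30, adjusted p = 0.131, above background on 2 of 6 SNEL arrays, with −3.99 within slide 1 and −1.01 within slide 2) and AI662270 (lower, of no measurable size, since it was above background on 0 of 6 SNEL arrays, adjusted p = 0.136). Lines did not overlap in 7.5% of genes, where chance gives 5.71%. With slide as a block limma called 11 genes, 2 higher and 9 lower, against 83 in the same fit without slide. Grem1 and Ascl2 were among the 11 but not Fgf22 (1.71, adjusted p = 0.57). Limma called 0 genes with the origin of the lines as a covariate, and 0 with only the groups compared. Within slides 1 and 2 the pluripotency median was 0.27 and 0.36, the germline median −0.78 and −1.23, the fibroblast median 0.39 and 0.22, and the ribosomal median 0.20 and 0.15. The count rested on single lines, with 346 genes, 72 higher and 274 lower, without Oct4-GFP SNEL#1, 10 without Oct4-GFP OSKM#2, 2 without KH2 ESCs, 1 without BC_2 OSKM and 0 without each of the other 6 lines, while Ascl2 passed adjusted over the list alone with any 1 line left out. The fibroblast median was 0.25 (adjusted p = 0.921) without Oct4-GFP SNEL#1 and 0.71 without Nanog-GFP SNEL#3, and did not pass without Nanog-GFP OSKM#2 (adjusted p = 0.102) or Oct4-GFP OSKM#2 (adjusted p = 0.0784). The germline median was −1.30 without Oct4-GFP SNEL#1 and did not pass without Nanog-GFP SNEL#2 (−0.36), Nanog-GFP SNEL#3 (−0.40), BC_2 OSKM (−0.64) or Oct4-GFP OSKM#2 (−0.78), and the pluripotency median was 0.15 without KH2_OSKM or Nanog-GFP SNEL#3. Grem1 did not pass in the authors' value table or after normexp background correction.

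The 8 reprogramming factors were measured from their own genes together with any transgene that holds the probe. Poor lines differed from ESC lines by 0.05 ± 0.45 (SE) in Pou5f1, which encodes Oct4, −0.07 ± 0.20 in Sox2, −0.27 ± 0.30 in Klf4, 0.49 ± 1.30 in Myc, −0.13 ± 0.22 in Sall4, −0.12 ± 0.22 in Nanog, −0.09 ± 0.17 in Esrrb and −0.61 ± 0.96 in Lin28a, each less than its error. SNEL lines differed from OSKM lines by −0.13 in Pou5f1, 0.27 in Sox2, 0.54 in Klf4, 0.34 in Myc, 0.30 in Sall4, −0.10 in Nanog, 0.17 in Esrrb and 0.44 in Lin28a, and 0 of the 8 passed. The Nanog probes ran from −0.10 to 0.50 in this comparison. In poor against ESC lines the 2 Nanog probes ran from −0.55 to −0.12 and the 3 Sall4 probes from −0.44 to −0.13. The values above are of the brightest probe. H2ax, which encodes the histone variant H2A.X of the DNA damage response, was 6.79 ± 0.48 (SD, n = 3) in poor, 6.72 ± 0.50 (n = 2) in good, 6.86 ± 0.31 (n = 2) in high and 6.84 ± 0.02 (n = 3) in ESC lines.

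The remaining lists passed camera's test in 0 of the 6 comparisons. As poor minus ESC medians they were −0.01 for the OSKM factors, −0.13 for the SNEL factors, 0.08 for other imprinted genes, −0.12 for primed epiblast, 0.05 for mesoderm, 0.17 for definitive endoderm, −0.26 for neuroectoderm, −0.01 for trophectoderm, −0.08 for ERK targets, −0.22 for Wnt targets, −0.01 for glycolysis and for oxidative phosphorylation, 0 for DNA methylation machinery, −0.02 for DNA damage response and H2A.X, and 0.29 for interferon and immune response. Of these the interferon list had the smallest adjusted p in that comparison, 0.0743. The median differed in sign from the mean or the test for the OSKM factors, trophectoderm, ERK targets, glycolysis, oxidative phosphorylation, DNA methylation machinery and DNA damage response and H2A.X. Definitive endoderm came nearest to the threshold in SNEL lines against OSKM lines, with a median of −0.61 (adjusted p = 0.0502).

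Chromosome medians describe whether the genes of a whole chromosome moved together in a line. Genes of chromosome 8 were higher than in the ESC lines by a median of 0.21 in Nanog-GFP OSKM#2 and, against the other ESC lines, by 0.172 in Oct4-GFP ESCs, over 1451 genes. The ESC reference of every iPSC line includes Oct4-GFP ESCs, which lowers their chromosome 8 medians. Without that ESC line the median of Nanog-GFP OSKM#2 was 0.264. Among the 190 medians of autosomes per line, the largest outside chromosome 8 was 0.06 in size. KH2_OSKM had 0.084 on chromosome 8, with a rise in part of it. Of 10 segments with like numbers of genes, the first 3 (3151667 to 48576052, mm9) had medians of 0.271, 0.282 and 0.369 in this line, and the others −0.099 to 0.076. No test was made, since each line is a single replicate here.

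**Figure D4:**
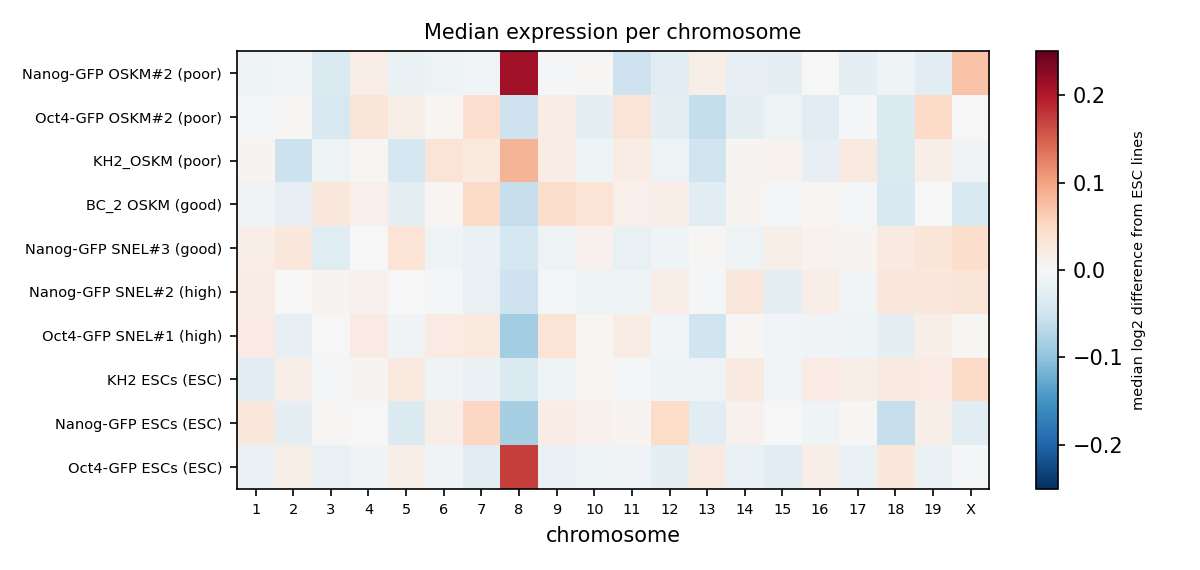
Median log2 difference from the ESC lines for each line and chromosome, from 1 to 19 and X, as a heat map. Chromosome 8 stands out in Nanog-GFP OSKM#2 (0.21) and in Oct4-GFP ESCs (0.172). The reference of the iPSC lines includes Oct4-GFP ESCs, which lowers their values on this chromosome.

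Sex-linked genes showed whether lines of a group differed in their sex chromosomes. Ddx3y, a Y-linked RNA helicase gene, ran from −1.20 to 1.00 in 7 lines, was −2.73 in KH2_OSKM and −3.06 in BC_2 OSKM, and was −8.29 in Nanog-GFP ESCs, where it was above background on 0 arrays. Eif2s3y, a Y-linked translation factor gene, was −8.11 in Nanog-GFP ESCs, −3.12 in BC_2 OSKM and −1.20 in KH2_OSKM, against 0.64 to 3.49 in the other lines. Xist, the RNA that coats an inactive X chromosome, was above background on 0 arrays. Its antisense gene Tsix ran from −4.82 to −2.28 over the lines.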

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

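The tests of Meg3 in the good lines against fibroblast RNA and of the fibroblast genes that are dim in good lines were chosen after the results were seen, and the other tests of this part before. Among 236 groups of arrays checked for a value far from the others, 3 were flagged. Chance flags about 1 in 20 groups of independent values. Each group here held 2 arrays per line, so that rate does not apply. The noncoding probe on chromosome 12 at 74139438 to 74139497 was −5.33 on array 2 of KH2_OSKM, against −3.80 to −3.04 on the other poor arrays. Fgf22 was −3.49 on array 1 of KH2 ESCs, against −3.20 to −3.08 on the other ESC arrays. The mean of the ribosomal protein list was 6.49 on array 2 of Oct4-GFP OSKM#2, against 6.55 to 6.59 on the other poor arrays. The difference between SNEL and OSKM lines differed between the Nanog-GFP and Oct4-GFP lines in 5 genes by a test of the interaction, which had 3 residual degrees of freedom, and 2094 genes had an unadjusted p under 0.05 there. Of its arms only Nanog-GFP SNEL holds more than 1 line, so the lone lines are assumed to vary like the other groups, and the calls can be properties of single lines. SNEL minus OSKM was well above 0 in Nanog-GFP lines and nearer 0 in Oct4-GFP lines for Zfp874a and a noncoding probe on chromosome 13. It was well below 0 in Nanog-GFP lines for Gm10499, which was above 0 in Oct4-GFP lines, and for DXBay18, which was nearer 0 there. Gm7748 was near 0 in Nanog-GFP lines and well above 0 in Oct4-GFP lines.

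Fibroblast genes, with Col1a2 at 1.46 in ESC lines and −2.99 in poor lines, were lower in poor lines, and RNA of fibroblasts left in some cultures is a candidate explanation, although the labels give culture without feeders. It predicts that a second list of abundant fibroblast genes falls as well, and 67.9% of its 28 genes were lower in poor lines, too few to meet that prediction and too many to exclude it. Among the 10 genes of that list that were dim in the good lines (a mean under −4), 90% were lower in poor lines, but the choice of genes largely fixed this, since 9 of them would pass the filter on ESC arrays alone and 1 on poor arrays alone, so it decides nothing. Of the other 18 genes of the second list 10 were lower, with a median of −0.03. A slide effect is argued against, since the median of the first list was −1.16 with slide effects removed. A difference in the cells' own expression between quality grades stays open and was not tested, so that and fibroblast RNA cannot be told apart here.

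Meg3 and Mirg were lower in poor lines, and fibroblast RNA in the other lines is argued against, because Meg3 was 5.65 in the lower of the 2 good lines, in which fibroblast genes were as low as in the poor lines. Slide is argued against as well, with a difference between poor and other lines of −3.91 on slide 1 and −3.97 on slide 2. A candidate explanation is silencing along the noncoding part of the Dlk1-Dio3 locus, since 85.7% of the 56 other probes between the 2 genes (chromosome 12, 110782745 to 110987628, mm9) were lower in poor than in good and high lines, with a median of −1.58. In the flanks the share was 45.7% of 81 probes, with a median of 0.13. Every poor line lay under every good and high line in 17 of the 56 probes, and in 1 of the 81. Many of these probes lie in the same few transcribed intervals, and some overlap, such as those at 110986374 to 110986433 and 110986389 to 110986448. The probes are repeated readings of the same lines and not independent of each other, so the shares carry less weight than their numbers. Probes that passed the filter through the other lines alone would tend to be lower in poor lines, and these were not counted. DNA methylation of the locus was not measured by these arrays, so silencing remains a hypothesis found and tested on the same data.

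Genes of chromosome 8 were higher in Nanog-GFP OSKM#2 and Oct4-GFP ESCs, and an array or slide effect is argued against, since the lowest of their 4 arrays lay 7.4 SDs of the other autosomes above 0. A few strong genes are argued against, since at least 67.7% of the chromosome's genes were above the median of the line. A gain of the whole chromosome in part or all of the cells is a candidate explanation, since 10 of 10 segments along it had a median above 0 in both lines, from 0.124 to 0.29 and from 0.123 to 0.253. The share of cells that such a gain would need was not measured. KH2_OSKM had medians of 0.271, 0.282 and 0.369 in the first 3 segments and −0.099 to 0.076 in the others, a rise in part of the chromosome that these tests did not cover. The design gives no biological group that both lines share.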

How the results depend on the processing

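Removal of slide effects, fits within slides, the fibroblast covariate, KH2_OSKM by its second array, the level filter, the all-line reference for chromosomes and the distance without fibroblast genes and genes that follow them were chosen after the data had been seen. Except where a cause is named, the cause was not tested. Every alternative was run. Counts of genes depended most on whether arrays or lines were the replicates. With the 20 arrays as independent samples, which counts each line more than once, limma called 277 genes for poor against ESC, 85 for good against ESC, 67 for high against ESC, 65 for high against poor, 172 for good and high against poor and 1222 for SNEL against OSKM. With the line as a random block the counts in this order were 40, 10, 5, 2, 6 and 83, and with array number as a further block 26, 5, 0, 2, 5 and 46. The labels do not say that array number marks a shared culture or day, and it was not used for pairing, since not every correlation between lines of the changes from array 1 to array 2 was over 0.1. But 29 of 45 were (−0.1 to 0.51, median 0.17), so part of these changes was shared. With slide as the block they were 11, 4, 0, 0, 4 and 11, and with slide effects removed 0 in all but SNEL against OSKM (3). Within slide 2, with 1 high array, whose spread is taken from other groups, limma called 1 gene for high against ESC and 1 for high against poor, which are no test of the grade either, and 69 for SNEL against OSKM, and within slide 3, which holds 1 high array and 3 ESC arrays, it called 11 for high against ESC, with the spread taken from the ESC arrays alone, so that these calls are no test of the grade. With the origin of the lines as a covariate, poor against ESC had 1 gene and SNEL against OSKM 0. With only the groups compared, high against ESC had 2 and SNEL against OSKM 0. SNEL against OSKM had 7 genes with quantile normalization, 6 with the fibroblast covariate, 1 with the filter of all 20 arrays and 0 with the mean of a gene's probes, in place of 2. Leaving out a line or an array number gave 0 to 2 genes for poor against ESC, 0 to 6 for good against ESC, 0 to 1 for high against ESC, for high against poor and for good and high against poor, and 0 to 346 for SNEL against OSKM, the last without Oct4-GFP SNEL#1.

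Of 144 list tests, 27 passed, against 0 with an estimated correlation, 17 after normexp and 50 with the fibroblast covariate. Over the alternatives, list medians kept their direction and side of the threshold 2898 times, no longer passed 122 times, newly passed 123 times, reversed 7 times and newly passed in the opposite direction 6 times. Ribosomal proteins in poor against ESC lines had a median of 0 with quantile normalization and 0 in the authors' value table, where the test turned. Naive and core pluripotency genes in good against ESC lines had −0.29 with the fibroblast covariate. With a line or an array number left out, core histones in good against ESC lines ran from −0.42 to 0, germline genes from −0.33 to 0.90 there and from −0.14 to 1.46 in high against ESC lines, and fibroblast genes from 0.25 to 0.71 in SNEL against OSKM lines. Named genes kept their direction and side of the threshold 4099 times, no longer passed 216 times, newly passed 75 times and, without a call, moved by more than their error or turned 342 times.

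The distance of iPSC lines beyond that of ESC lines was 0.093 with the filter of all 20 arrays (exact p = 0.05), and ran from 0.051 to 0.308 with a line or an array number left out. The distance of poor lines beyond good and high lines was −0.003 with the filter of all 20 arrays and −0.023 against the ESC line of the same origin, and ran from −0.009 to 0.054 with a line or an array number left out. The chromosome 8 median of Nanog-GFP OSKM#2 was 0.142 after normexp, 0.177 in the authors' value table, 0.155 with no filter and 0.165 against the median of all 10 lines, and ran from 0.164 to 0.264 with a line or an array number left out. That of Oct4-GFP ESCs was 0.109 after normexp, 0.133 in the authors' value table, 0.196 with the filter of all 20 arrays, 0.201 with a mean level above −3 and 0.125 against the median of all 10 lines, and ran from 0.146 to 0.18. Grem1, above background on no OSKM array, did not pass in the value table or after normexp.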

Other observations

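The test of the first axis of variation was chosen after the data had been seen, and the splits of the lines before. Lineage genes varied between lines in ways that the quality grades did not follow. The first principal component of the 10 lines held 36.7% of the variance and ran from BC_2 OSKM (72.1), KH2_OSKM (68.8) and Oct4-GFP SNEL#1 (58) to Nanog-GFP SNEL#2 (−53.8) and Nanog-GFP SNEL#3 (−79.2), with ESC lines at 30.2, −38.7 and −53.6. Across the 10 lines, the mean of the definitive endoderm list rose with it (r = 0.93, permutation adjusted p = 0.0015, rho = 0.9, permutation adjusted p = 0.00575), and r was 0.97 without the 2 lines farthest from the median. Glycolysis genes also rose with it (r = 0.92, permutation adjusted p = 0.00292, rho = 0.92, permutation adjusted p = 0.0045, r = 0.87 without the 2 farthest lines). The mean of the SNEL factor list fell with it (r = −0.93, permutation adjusted p = 0.00162, rho = −0.88, permutation adjusted p = 0.0095, r = −0.94 without the 2 farthest lines), and so did neuroectoderm genes (r = −0.82, permutation adjusted p = 0.003, rho = −0.94, permutation adjusted p = 0.0045, r = −0.87 without the 2 farthest lines). Lin28a went with the fall of the SNEL factor list, at 5.27 in Nanog-GFP SNEL#3 and 4.99 in Nanog-GFP SNEL#2 against 2.94 in BC_2 OSKM, 2.74 in KH2_OSKM and 2.10 in Oct4-GFP SNEL#1. Nanog did not, at 6.52 and 6.62 against 6.99, 6.88 and 7.22 in the same lines. In all, 14 of the 25 lists had an adjusted p of r under 0.05, adjusted over the 25, and these 4 had the smallest, while 10 of the 25 passed by both r and rho. The OSKM factors were among the 14 (r = −0.76, permutation adjusted p = 0.0285, rho = −0.75, permutation adjusted p = 0.0446, r = −0.64 without the 2 farthest lines), so the relation is not particular to the SNEL factors. The raw permutation p of r of the 4 were 6e-05, 0.00035, 0.00013 and 0.00048, and those of rho 0.00069, 0.00036, 0.00152 and 0.00021. The component was computed without the genes of the lists but from the same arrays, so these relations describe it and are no independent evidence. The fibroblast list did not follow it (r = 0.09, permutation p = 0.799, rho = 0.12, permutation p = 0.76, r = −0.04 without the 2 farthest lines), nor did the percent of spots well above background (r = 0.48, permutation p = 0.152, rho = 0.42, permutation p = 0.233, r = 0.3 without the 2 farthest lines).

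Two-cell-like and germline genes differed between lines of the same grade. Relative to the mean of the 10 lines, their mean was 2.99 in Oct4-GFP SNEL#1 and −1.48 in Nanog-GFP SNEL#2, both of high grade, 0.79 in BC_2 OSKM and −1.94 in Nanog-GFP SNEL#3, both of good grade, and 0.20 in Nanog-GFP ESCs against −2.09 and −1.95 in the other ESC lines. Germline genes were at 0.97 in Oct4-GFP SNEL#1, 0.44 in BC_2 OSKM and 0.41 to 0.90 in the poor lines, against −0.84 in Nanog-GFP SNEL#2 and −0.69 in Nanog-GFP SNEL#3.

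Other splits of the lines into groups of the same sizes were counted for the comparisons with at least 3 lines on each side. Poor against ESC lines has only 10 splits, too few for a share under 0.05, and called 0 genes where the highest other split called 1. For good and high against poor lines the real split also called 0 genes, and the highest other 262, in a fit whose groups were the 2 sides and the ESC lines. All of the splits (10 of 10 and 35 of 35) had to give at least 0 genes, so these counts say nothing about chance. For SNEL against OSKM lines, 7 of 35 splits gave at least the 2 genes of the real split, which leaves chance open for that count. There the highest other was the same split in the same fit, and so the same 262 genes, for the 3 Nanog-GFP iPSC lines against the other 4. Both comparisons divide the same 7 lines into 4 and 3. That split calls many times the real count and points to a structure of the lines, but it was picked as the highest and what the structure follows was not tested.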
